A study of Mus musculus with 6 samples.

How the data were processed

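RNA was profiled in cultured mouse OPCs, 3 samples exposed to vehicle and 3 to hemin for 12 h. Per the labels' protocols, RNA was extracted with Trizol, mRNA was enriched, amplified by PCR and made into Illumina libraries; whether the libraries keep strand is not given in the sources used here. Samples were assigned to groups by their titles. The submitters' processing notes name Bowtie 0.12.2 and RSEM, without a version for the latter, and the builds mm8 and mm9 with no role or order. The annotation release, the method that made the unannotated features, read filters and trimming are not given in the sources used here. Because the build in use is open, no coordinates are printed.

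Each library has a table of annotated transcripts and a table of unannotated features, which the authors keep apart. Per the file headers, both hold expected counts, the authors' estimates of reads per transcript that need not be whole and are not scaled for depth, and FPKM, which the authors scaled by feature length and by library size. The tables list only features above 0, so a gene missing from a table was set to 0. Annotated transcripts numbered 26421 in any library and 16085 in every library. They were summed to 18743 genes by the gene identifiers in the files, of which 18711 matched a symbol in the RefSeq gene table of assembly GRCm38.p6 and 32 did not. That table was used only for names and for which genes neighbour each other, with the strand and exons taken from GENCODE vM21.

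Before the data were examined, the groups, tests, gene lists, rule for named genes and most alternatives were fixed. The plan assumed FPKM values and named a count test in case the files held counts. They hold expected counts, so the count test is the main one and limma on FPKM an alternative. Expected counts were summed per gene and rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 filtered genes with filterByExpr by group, computed TMM factors and tested hemin against vehicle with the quasi-likelihood functions glmQLFit and glmQLFTest, without covariates, two-sided, with Benjamini-Hochberg adjustment over the 12779 genes left. The filter can be passed through the counts of 1 group alone, so among genes near 0 with vehicle it favours rises. Calls are at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of the test's F. The biological coefficient of variation was 0.208. Where one group had 1 to 3 counts, the ratio of summed counts is given with a 95% interval that covers counting error only, since PCR reads without molecular identifiers are not independent molecules. Unannotated features with a mean FPKM of at least 0.5 were tested in the same way with the library sizes of the annotated genes and adjusted on their own.

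The 29 lists cover heme, iron, ferroptosis, stress, protein quality, metabolism, proliferation, death, inflammation and cell type markers, and were written from textbook knowledge. The 27 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log-scaled CPM with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 27 lists. Camera asks whether a list's genes move differently from the other genes. Beside it, the correlation was estimated per list, and fry tested whether a list's genes move one way on balance. Calls of members are given over all genes tested and adjusted over the list alone.

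Named genes are the 8 with the greatest rise and the 8 with the greatest fall among called genes whose groups do not overlap and whose mean is at least 5 FPKM in the higher group, 13 fixed genes (Hmox1, Fth1, Ftl1, Tfrc, Slc40a1, Slc7a11, Gpx4, Acsl4, Ptgs2, Chac1, Nqo1, Pdgfra and Mbp), and per list up to 4 members with the smallest p and the largest against its direction. Provisional names and multi-copy globin-like genes were passed over. Vkorc1l1, Hsd17b7, Pmvk, Xiap, Cox5a, Cox6a1, Clu, Nefl and Elavl4 fall outside the rule. They are named because 5 or fewer members of their list moved that way, so they were chosen after their values were seen. Some genes that the rule selects are not reported here.

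The tests were tried on simulated data with the real genes' means and spread and 100 genes changed at each fold size. Among the 12779 simulated genes of this comparison edgeR recovered 53% of 2-fold and 87% of 4-fold changes, with 6.58% of its calls false. DESeq2 1.42.0 recovered 68% and 91% with 23.3% false, and limma 49% and 87% with 6.12% false. The real comparison called 4077 genes, far more than were changed in the simulation, so these shares need not carry over to it. In the simulated list test, camera gave an adjusted p of 4.01e-16 for a list of 25 genes raised 1.5-fold and called 0 of 20 unshifted lists. Matching means and spread does not reproduce genes of a list that move together, so 0 of 20 gives no error rate for such lists.

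Alternatives were limma on log2(FPKM + 1) with and without a trend, pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, DESeq2's size factors, upper-quartile scaling, quantile normalization, DESeq2, robust fits, the replicate number as a block, an adjusted p below 0.01, a change of at least 2-fold, the most abundant transcript per gene, and leaving out each library in turn. Library totals without TMM, leaving out genes at 0 in single libraries or in a whole group but well counted in others, and limma for the unannotated features were added after the data were seen. Figures and the checks of neighbouring genes were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.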

Results

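Oligodendrocyte progenitor cells (OPCs), the dividing glial precursors that give rise to myelinating oligodendrocytes, were isolated from neonatal C57BL/6 mouse cortex with magnetic beads against CD140a (PDGFRα), a receptor on their surface. After 3 days of expansion they received 50 µM hemin, the oxidised iron-containing form of heme, or 0.25% DMSO as vehicle, for 12 h. RNA-seq libraries were made from 3 vehicle and 3 hemin samples. The title of the series places the experiment in a study of ferroptosis, an iron-dependent death by lipid peroxidation, after bleeding in the brain. The comparison therefore asks which transcripts differ after exposure to hemin, those of heme, iron and lipid peroxide metabolism among them. Nothing in the labels says that the replicates came from separate cultures or litters, so the p-values measure only the spread between these samples, which may be technical.

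Expected counts over annotated genes summed to 6339966, 6390691 and 6354174 in vehicle replicates 1 to 3 and to 6518538, 6523639 and 6463460 in hemin replicates 1 to 3. The vehicle libraries listed 15474, 15388 and 15500 genes and the hemin libraries 16719, 16897 and 16866. Pearson's r of log-scaled CPM across genes, which are not independent replicates, was 0.957 to 0.964 between vehicle libraries, 0.941 to 0.955 between hemin libraries and 0.885 to 0.905 across the groups. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 5.35 to 21.7 within groups, so no library was counted as a duplicate.

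Single genes of heme degradation, cystine uptake and prostaglandin synthesis rose with hemin, and the receptor used for the isolation fell. Hmox1 (gene identifier 15368 in the files), the heme oxygenase that breaks heme down and frees its iron, rose 126-fold, from 21.5 ± 6.61 to 2599.6 ± 393 FPKM (SD, n = 3 per group). Slc7a11 (26570), the cystine importer that feeds glutathione synthesis, rose 28.2-fold, from 3.50 ± 0.972 to 95.04 ± 31.3 FPKM. Ptgs2 (19225), the inducible cyclooxygenase often read as a sign of ferroptosis, rose 178-fold, from 0.113 ± 0.0404 to 20.4 ± 1.11 FPKM. Pdgfra (18595), that receptor, fell 4.93-fold, from 120.3 ± 24.2 to 23.7 ± 9.92 FPKM. Of 12779 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 4077 (31.9%) passed an adjusted p of 0.05, 2072 higher and 2005 lower with hemin. The change was at least 2-fold for 955 of the higher and 742 of the lower genes. The 3 libraries of one group lay entirely above those of the other for 6252 genes, 48.9% of those tested, against 10% by chance. With libraries scaled by their totals alone, an alternative added after the data were seen, 1715 genes rose and 2582 fell, which moved the share of higher calls from 50.8% to 39.9%. The count dropped to 2597 without vehicle replicate 1 and to 2551 without vehicle replicate 2.

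**Figure D1:**
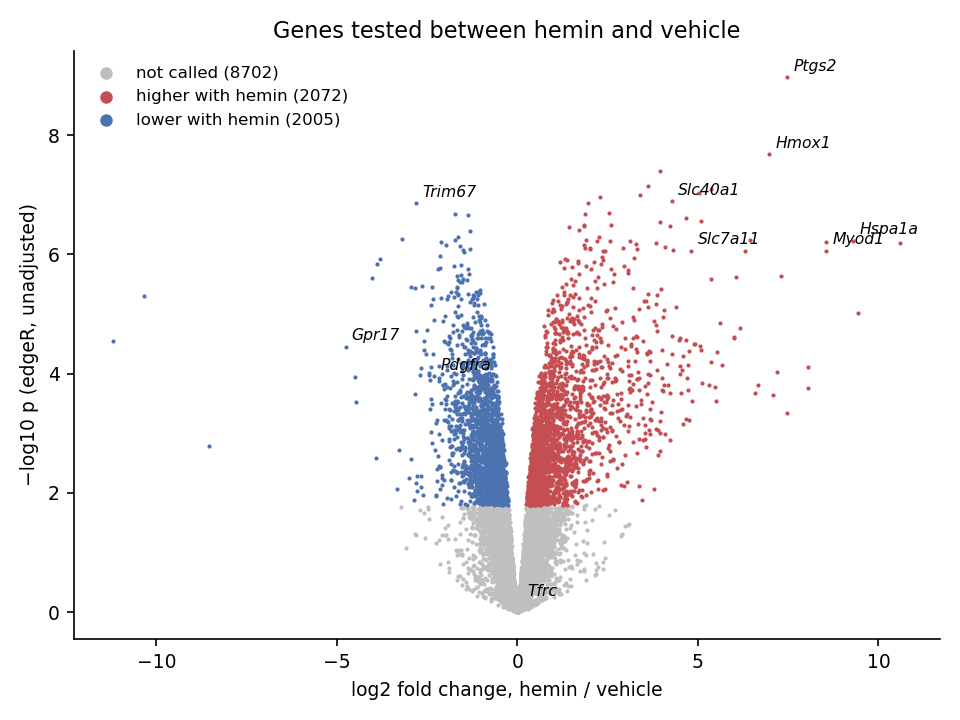
Log2 fold change of hemin over vehicle on the horizontal axis and minus log10 of the unadjusted edgeR p on the vertical axis, 1 point per gene tested. Red points are the 2072 genes higher and blue points the 2005 genes lower with hemin at an adjusted p under 0.05, with Ptgs2 and Hmox1 at the top right.

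The genes with the greatest rises included several that respond to stress. Hspa1a and Hspa1b, near-identical copies of the inducible Hsp70 chaperone between which the authors' counting could split reads, stood at 0.570 ± 0.252 and 0.720 ± 0.125 FPKM with vehicle and at 344 ± 167 and 262 ± 125 FPKM with hemin (log2 fold change 9.30 ± 0.60 and 8.55 ± 0.56, SE). Hspa1b lies downstream of a gene on the same strand that counted as expressed by its mean over all 6 libraries, which hemin itself can raise. Atf3, a stress-induced transcription factor, rose by 6.45 ± 0.41 on the log2 scale, and Osgin1, an inhibitor of growth induced by oxidative stress, by 6.30 ± 0.43. Myod1, the transcription factor that sets the skeletal muscle programme, had 1 count over the 3 vehicle libraries and 498 over the 3 hemin libraries, a ratio of 520 with a 95% counting interval from 92.8 to 20566. These 5 genes, Ptgs2 and Hmox1 had edgeR adjusted p-values from 1.38e-05 to 0.000199.

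The genes with the greatest falls included markers of the oligodendrocyte and neuronal lineages and a target of Notch signalling. Gpr17, a receptor of precursors committed to the oligodendrocyte fate, fell 27.1-fold, from 23.3 ± 11.5 to 0.823 ± 0.437 FPKM. Omg, the oligodendrocyte myelin glycoprotein, fell 14.8-fold, Tmem100, a membrane protein on the list of progenitor markers, 13.9-fold, and Hes5, a transcriptional repressor induced by Notch, 7.66-fold. Neurod6 and Bhlhe22, transcription factors of cortical neurons, fell 16.2-fold and 9.21-fold, and Trim67, a ubiquitin ligase of the nervous system, 7.02-fold. The edgeR adjusted p-values of these 7 genes lay between 0.000162 and 0.00121. Dnttip2, a nucleolar protein, had 538, 594 and 576 counts with vehicle and 58, 166 and 0 with hemin (edgeR adjusted p = 0.0436). Its call was lost without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.102, 0.104 and 0.091) and without hemin replicate 1 (0.0837), with the replicate number as a block (0.0513) and in limma after quantile normalization (0.0562), and the 0 can be a failed estimate of the counting.

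**Figure D2:**
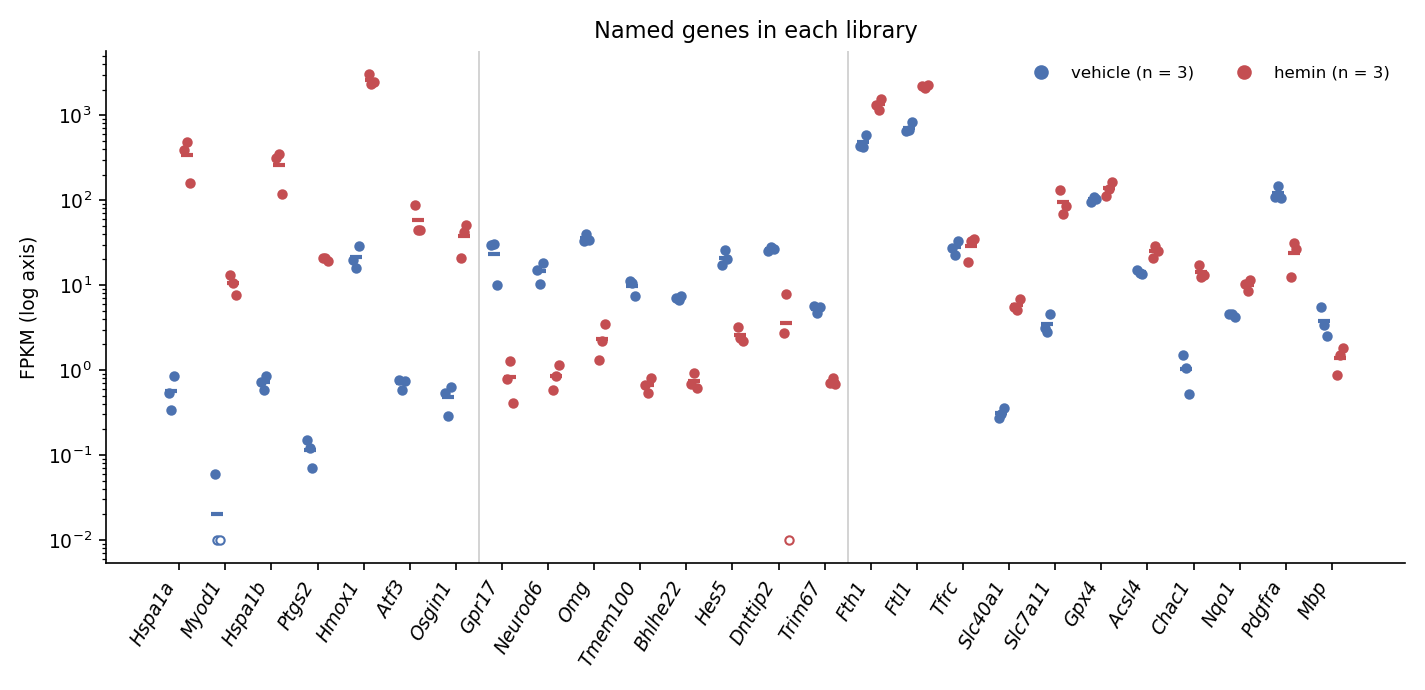
FPKM on a log axis for each named gene in the 3 vehicle (blue) and 3 hemin (red) libraries. Points are libraries, horizontal bars are group means, and open points are libraries whose tables lack the gene, set to 0 and drawn at 0.01. From left to right stand 7 genes with the greatest rises, the 8 with the greatest falls and the fixed genes, with Hmox1 at 2599.6 FPKM on average with hemin.

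Of 27 gene lists tested with camera, 19 passed, 16 with higher and 3 with lower members. Other splits of the same 6 libraries, which mix the treatments, gave up to 16. Genes of heme breakdown and iron handling rose, whereas the receptor for iron uptake did not pass the test. Of 28 tested members, 11 rose and 1 fell, over all genes tested and likewise adjusted over the list alone, and the median log2 fold change was 0.29 (camera adjusted p = 0.000984, and an adjusted p of 0.113 with an estimated correlation). Ferritin heavy and light chains, which store iron, rose 2.91-fold (Fth1, 478 ± 87.3 to 1339 ± 203 FPKM) and 3.18-fold (Ftl1, 714 ± 96.6 to 2186 ± 109 FPKM), values that can include reads of their processed copies. Slc40a1, the iron exporter ferroportin, rose 19.3-fold from 0.310 ± 0.0458 to 5.82 ± 0.851 FPKM, and Blvrb, a biliverdin reductase, 2.95-fold. Tfrc, the transferrin receptor, stood at 27.8 ± 5.23 FPKM with vehicle and 28.9 ± 8.71 with hemin (log2 fold change 0.09 ± 0.23, edgeR adjusted p = 0.785). Hmox2, the constitutive heme oxygenase, fell 1.41-fold, a call lost without vehicle replicate 1 or 2 (edgeR adjusted p = 0.0748 and 0.0554). Of 9 genes of heme biosynthesis, 2 rose and 1 fell, again the same counts adjusted over the list alone, with a median of 0.06 that turned to -0.03 when scaled by totals alone (camera adjusted p = 0.954). Alas1, the rate-limiting enzyme of the pathway, fell 2.23-fold from 11.2 ± 0.222 to 4.86 ± 0.565 FPKM. The 2 that rose were Ppox and Abcb6, a late enzyme and a porphyrin transporter, by 2.19-fold and 1.38-fold. Both calls were lost with totals alone (edgeR adjusted p = 0.0613 and 0.0617), without vehicle replicate 1 (0.134 and 0.11), vehicle replicate 2 (0.132 and 0.0774) or hemin replicate 2 (0.0915 and 0.113), that of Ppox also without hemin replicate 3 (0.133) and that of Abcb6 without vehicle replicate 3 (0.0785) or hemin replicate 1 (0.0604) and with the replicate number as a block (0.0523).

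The list of genes that protect cells from ferroptosis and the list of genes that promote or mark it both rose as groups. Of 22 tested defence genes, 12 rose and 1 fell, as they did adjusted over the list alone, with a median log2 fold change of 0.40 (camera adjusted p = 0.000965, and an adjusted p of 0.0988 with an estimated correlation). Besides Slc7a11, its partner chain Slc3a2 rose 4.47-fold, Gclm, a subunit of the enzyme that limits glutathione synthesis, 8.62-fold, and Txnrd1, a thioredoxin reductase, 4.35-fold. Gpx4, the peroxidase that reduces lipid hydroperoxides, stood at 102 ± 6.26 FPKM with vehicle and 138 ± 26.4 with hemin (1.39-fold, edgeR adjusted p = 0.0289). That call was lost with totals alone (edgeR adjusted p = 0.0703), with limma after quantile normalization (0.0664) or at a pseudocount of 0.1 (0.0599), and without vehicle replicate 1, 2 or 3 (0.106, 0.0728 and 0.0672) or hemin replicate 2 or 3 (0.0705 and 0.0622). Vkorc1l1, a vitamin K reductase, fell 1.54-fold. Dhodh, a mitochondrial dehydrogenase, had 0, 113 and 64 counts with vehicle and 18, 20 and 0 with hemin and did not pass (edgeR adjusted p = 0.272). Of 22 genes on the ferroptosis-promoting list, which also holds Ptgs2, a sign of ferroptosis, 11 rose, 12 adjusted over the list alone. Over all genes tested 11 did not pass, Tfrc among them. The median was 0.30 (camera adjusted p = 0.0001, and an adjusted p of 0.0988 with an estimated correlation). Next to Ptgs2, the glutathione-degrading enzyme Chac1 rose 14.4-fold, Sat1, which breaks down polyamines, 2.03-fold, Por, a cytochrome reductase, 1.71-fold, and Acsl4, which loads polyunsaturated fatty acids into lipids, 1.80-fold from 14.2 ± 0.885 to 24.9 ± 4.29 FPKM. Fads2, a fatty acid desaturase, stood at 121 ± 11.7 FPKM with vehicle and 106 ± 12.3 with hemin (edgeR adjusted p = 0.374). Hmox1, Slc7a11, Ptgs2, Chac1 and the ferritins belong to several of the lists, which are therefore not independent of each other.

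Targets of NRF2, the transcription factor of the antioxidant response, and genes of the integrated stress response rose together. Of 29 tested NRF2 targets, 24 rose, 25 adjusted over the list alone, with a median log2 fold change of 1.23 (camera adjusted p = 2.44e-12, and an adjusted p of 0.187 with an estimated correlation). Sqstm1, an autophagy receptor, rose 9.94-fold from 64.4 ± 12.0 to 614 ± 133 FPKM, and Nqo1, a quinone reductase, 2.35-fold from 4.45 ± 0.255 to 10.1 ± 1.503 FPKM. Ugdh, which makes a precursor of glucuronides, stood at 62.6 ± 10.3 FPKM with vehicle and 43.6 ± 17.3 with hemin (edgeR adjusted p = 0.235). Of 31 genes of the integrated stress response, 27 rose, 28 adjusted over the list alone, with a median of 1.68 (camera adjusted p = 4.38e-13, and an adjusted p of 0.246 with an estimated correlation). Gdf15, a secreted stress cytokine, rose 41.0-fold, Ppp1r15a, which restores translation, 18.7-fold, and Ddit3, a transcription factor of prolonged stress, 15.4-fold to 104 ± 19.1 FPKM.

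Heat shock proteins, most proteasome subunits and part of the lysosomal and endoplasmic reticulum genes were higher with hemin. Of 20 heat shock proteins, 20 rose, as they did adjusted over the list alone, with a median log2 fold change of 1.32 (camera adjusted p = 1.19e-10, and an adjusted p of 0.218 with an estimated correlation). Bag3, a co-chaperone, rose 4.02-fold, and Hspa8, the constitutive Hsp70, 2.47-fold from 1288 ± 83.4 to 3060.3 ± 269 FPKM, a call that quantile normalization ended (log2 fold change 0.12, limma adjusted p = 0.436). Of 31 proteasome subunits, 25 rose, 27 adjusted over the list alone, by smaller amounts, with a median of 0.51 (camera adjusted p = 3.92e-08, and an adjusted p of 0.282 with an estimated correlation). Psmd11 and Psmd4 of the regulatory particle rose 2.06-fold and 1.72-fold, and Psmc2 stood at 17.6 ± 10.1 FPKM with vehicle and 15.4 ± 16.0 with hemin. Of 20 chaperones and degradation factors of the endoplasmic reticulum, 7 rose and 13 did not pass. Adjusted over the list alone 10 rose and 1 fell. The median was 0.26 (camera adjusted p = 0.0097, and an adjusted p of 0.136 with an estimated correlation). Dnajb9, a co-chaperone, rose 3.76-fold, Herpud1, a degradation factor, 4.24-fold, Xbp1, a transcription factor of the unfolded protein response, 2.55-fold and the chaperone Hspa5 2.48-fold, while Sdf2l1, a further luminal factor, was 8.34 ± 1.98 FPKM with vehicle and 5.86 ± 1.59 with hemin (edgeR adjusted p = 0.245). Of 23 autophagy and lysosome genes, 13 rose, the same number adjusted over the list alone, with a median of 0.43 (camera adjusted p = 2.62e-05, and an adjusted p of 0.0988 with an estimated correlation), among them the hydrolases Gla, 2.89-fold, and Ctsl, 1.70-fold. Markers of microglia, cells rich in lysosomes, moved in the same direction (median 0.81). Of 6 metallothionein and zinc export genes, 2 rose, 2 also adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.0421, and an adjusted p of 0.291 with an estimated correlation). These were the manganese and zinc exporter Slc30a10, with 3 counts over the vehicle and 145 over the hemin libraries (ratio 50.4, 95% counting interval 16.9 to 247), and the metal-responsive transcription factor Mtf1, 1.41-fold higher. The call of this list was lost without vehicle replicate 1 or 2 (camera adjusted p = 0.0947 and 0.0729) or hemin replicate 1 or 3 (0.101 and 0.0842).

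**Figure D3:**
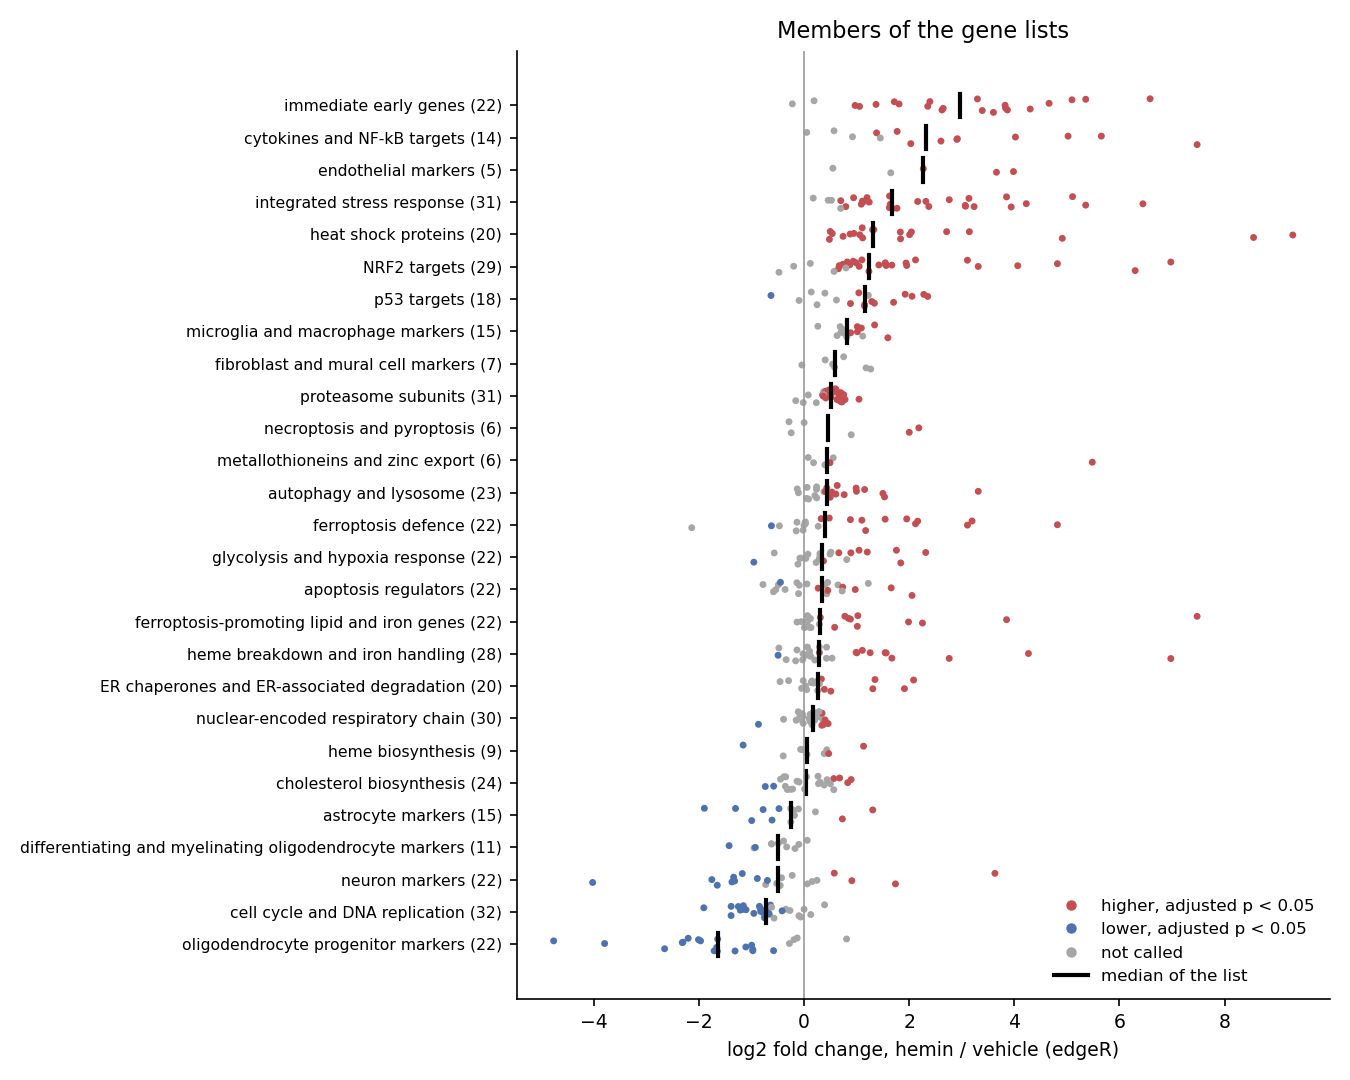
Log2 fold change of hemin over vehicle for each tested member of the 27 lists with at least 5 tested members, ordered by median. Points are genes, coloured by their edgeR call, black bars are list medians, and the number of tested members is in brackets. Medians run from -1.65 for progenitor markers to 2.97 for immediate early genes.

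Progenitor markers fell, and few genes of later oligodendrocyte stages could be tested. Of 22 tested OPC markers, 18 fell, as they did adjusted over the list alone, with a median log2 fold change of -1.65 (camera adjusted p = 1.53e-08, and an adjusted p of 0.218 with an estimated correlation). Besides Pdgfra, Gpr17 and Tmem100, Dll3, a Notch ligand, fell 6.29-fold from 24.6 ± 6.20 to 3.76 ± 0.437 FPKM, and Sox8, a transcription factor of the lineage, 3.12-fold. Pcdh15, a protocadherin, stood at 1.22 ± 0.550 FPKM with vehicle and 2.18 ± 1.91 with hemin (edgeR adjusted p = 0.374). Of 11 tested markers of differentiating and myelinating oligodendrocytes, 2 fell, as they did adjusted over the list alone, and the list did not pass (median -0.49, camera adjusted p = 0.0918). It passed without vehicle replicate 3 (camera adjusted p = 0.00875). The 2 were Ugt8a, which makes myelin galactolipids, 1.90-fold lower, and Mbp, myelin basic protein, 2.69-fold lower at 3.80 ± 1.55 FPKM with vehicle and 1.40 ± 0.472 with hemin. The Mbp call was lost without vehicle replicate 1 or hemin replicate 2 (edgeR adjusted p = 0.0652 and 0.0524) and with the replicate number as a block (0.0518). Cldn11, a tight junction protein of myelin, stood at 5.44 ± 1.83 and 2.72 ± 1.21 FPKM.

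Genes of the cell cycle fell, and targets of p53, the transcription factor activated by DNA damage and other stress, rose. Of 32 cell cycle and DNA replication genes, 23 fell, 26 adjusted over the list alone, with a median log2 fold change of -0.73 (camera adjusted p = 1.11e-08, and an adjusted p of 0.218 with an estimated correlation). The replicative helicase subunits Mcm3, Mcm2 and Mcm4 fell 2.23-fold, 1.80-fold and 1.69-fold, and Ccne1, the cyclin of entry into S phase, 3.75-fold. Ccnb2, a mitotic cyclin, stood at 27.4 ± 3.99 FPKM with vehicle and 34.8 ± 13.01 with hemin and was called higher without hemin replicate 1 (log2 fold change 0.65, edgeR adjusted p = 0.0144). Of 18 p53 targets, 11 rose and 1 fell, 13 and 1 adjusted over the list alone, with a median of 1.15 (camera adjusted p = 8.02e-05, and an adjusted p of 0.297 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose 5.11-fold from 73.6 ± 14.3 to 361 ± 97.1 FPKM, the death receptor Fas 4.85-fold, Mdm2, which degrades p53, 3.79-fold and the kinase Plk2 2.53-fold. Sesn1, a sestrin, fell 1.55-fold, a call lost without vehicle replicate 1 or 2 or hemin replicate 2 (edgeR adjusted p = 0.0702, 0.0609 and 0.0565).

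Regulators of apoptosis and necroptosis did not pass as groups, although single members rose. Of 22 apoptosis regulators, 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median log2 fold change of 0.33 (camera adjusted p = 0.224, fry adjusted p = 0.0489). The pro-apoptotic Pmaip1 rose 4.15-fold and Bcl2l11 3.16-fold, the anti-apoptotic Mcl1 1.67-fold, and Cflar, which restrains caspase activation at death receptors, 1.96-fold. Xiap, an inhibitor of caspases, fell 1.36-fold, a call lost without vehicle replicate 1, 2 or 3 (edgeR adjusted p = 0.0673, 0.0636 and 0.0518). Hrk, a pro-apoptotic factor, stood at 1.58 ± 0.302 and 0.877 ± 0.429 FPKM and was called lower without hemin replicate 1 (edgeR adjusted p = 0.0146). Of 6 tested necroptosis and pyroptosis genes, 2 rose, 2 also adjusted over the list alone, with a median of 0.45 (camera adjusted p = 0.324, fry adjusted p = 0.0106), beside the median of 0.81 of microglial markers. The 2 were Mlkl, which opens the membrane in necroptosis, 4.54-fold, and its activating kinase Ripk3, 4.00-fold from 0.267 ± 0.0929 to 1.05 ± 0.539 FPKM. The Ripk3 call was lost with quantile normalization (limma adjusted p = 0.0985) and without vehicle replicate 1 or 3 or hemin replicate 2 (edgeR adjusted p = 0.0746, 0.0602 and 0.0662).

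Immediate early genes and inflammatory mediators showed the largest median rises among the lists of processes. Of 22 immediate early genes, which respond to stimuli without new protein synthesis, 20 rose, as they did adjusted over the list alone, with a median log2 fold change of 2.97 (camera adjusted p = 4.89e-13). It was the only list that also passed with an estimated correlation (camera adjusted p = 0.0305). Egr1 rose 25.3-fold from 14.0 ± 2.21 to 345 ± 110.0 FPKM, Fosl1 34.2-fold, Arc 14.2-fold and Maff 10.5-fold, while Myc stood at 31.8 ± 1.86 and 26.3 ± 2.21 FPKM (edgeR adjusted p = 0.17). Of 14 tested cytokines and NF-kB targets, 10 rose, 12 adjusted over the list alone, with a median of 2.32 (camera adjusted p = 6.9e-08, and an adjusted p of 0.0988 with an estimated correlation). Next to Ptgs2, the chemokine Cxcl10 rose 32.5-fold from 0.517 ± 0.0666 to 16.6 ± 2.76 FPKM, Nfkbiz, a nuclear regulator of NF-kB, 7.55-fold, and Csf1, a growth factor of microglia, 6.08-fold. Microglial markers rose beside this list as well, but by less, with a median of 0.81 against 2.32. A larger share of microglial RNA alone would not account for a median rise of that size. Which cells made these transcripts was not tested.

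Among the metabolic lists, the joint list of glycolysis and hypoxia genes passed, and cholesterol biosynthesis and the respiratory chain did not. Of 22 glycolysis and hypoxia genes, 8 rose and 1 fell, 9 and 1 adjusted over the list alone, with a median log2 fold change of 0.34 (camera adjusted p = 0.00332, and an adjusted p of 0.218 with an estimated correlation). Over all genes tested 13 did not pass, glycolytic enzymes among them. The call of the joint list therefore speaks for neither process alone. The glucose transporter Slc2a1 rose 3.58-fold, Adm, a vasodilator peptide induced by hypoxia, 4.97-fold, P4ha1, a collagen prolyl hydroxylase, 2.07-fold and the glycolytic enzyme Aldoa 1.85-fold, while Egln1, the oxygen sensor that marks HIF for degradation, fell 1.94-fold. Of 24 tested genes of cholesterol biosynthesis, 4 rose and 2 fell, as they did adjusted over the list alone, with a median of 0.03 that was -0.06 when scaled by totals alone (camera adjusted p = 0.875). Cyp51, Hsd17b7 and Pmvk rose 1.86-fold, 1.78-fold and 1.60-fold, and Acat2 and Sqle fell 1.67-fold and 1.49-fold, all enzymes of the pathway. Except for Cyp51 these calls were lost without vehicle replicate 2 (edgeR adjusted p from 0.0533 to 0.0943), those of Acat2, Hsd17b7 and Pmvk without vehicle replicate 1 (0.0522 to 0.0894), those of Hsd17b7 and Pmvk without hemin replicate 2 or 3 (0.0736 to 0.0906), and that of Pmvk without vehicle replicate 3 (0.0759), with totals alone (0.0502) or with the replicate number as a block (0.0624). The Hsd17b7 call was also lost with limma at a pseudocount of 0.1 (adjusted p = 0.0514). Of 30 nuclear genes of the respiratory chain, 5 rose and 1 fell, 2 and 1 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.102), and the list passed without hemin replicate 1 (camera adjusted p = 0.00515). Sdhd, a membrane anchor of succinate dehydrogenase, fell 1.82-fold. Cox4i1, Cox6a1, Cox5b, Cox5a and Sdhb rose 1.26-fold to 1.37-fold, calls that were all lost without vehicle replicate 2 (edgeR adjusted p from 0.0603 to 0.143) or hemin replicate 2 (0.0507 to 0.136) and, except for Cox4i1, without vehicle replicate 1 or 3 or hemin replicate 3 (0.0562 to 0.135) and with totals alone (0.0675 to 0.134). Those of Sdhb, Cox5a and Cox6a1 were also lost with limma at a pseudocount of 0.1 or after quantile normalization (adjusted p from 0.106 to 0.117), and in edgeR with the replicate number as a block (0.0619, 0.0721 and 0.0501). None of the 13 mitochondrially encoded genes on the fixed list was listed in the files used here.

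Markers of other cell types moved in different directions. Of 15 tested markers of microglia and macrophages, 6 rose, the same number adjusted over the list alone, with a median log2 fold change of 0.81 (camera adjusted p = 3.21e-05, and an adjusted p of 0.282 with an estimated correlation). Cd68, a lysosomal glycoprotein, rose 3.02-fold from 5.06 ± 1.08 to 14.4 ± 3.10 FPKM and lysozyme Lyz2 2.02-fold. Ctss and Itgam, a protease and an integrin of these cells, rose 1.85-fold and 2.13-fold, both lost without vehicle replicate 2 (edgeR adjusted p = 0.063 and 0.071) or 3 (0.052 and 0.0558) and Itgam also without hemin replicate 2 (0.0667). Of 22 neuron markers, 4 rose and 9 fell, 4 and 11 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.0209, and an adjusted p of 0.297 with an estimated correlation). Dcx, a microtubule protein of migrating neuroblasts, fell 2.26-fold and Tbr1, a transcription factor of cortical neurons, 3.37-fold, whereas the neurofilament chains Nefm and Nefl rose 12.4-fold and 3.34-fold. Elavl4, a neuronal RNA-binding protein, rose 1.49-fold. The Elavl4 call was lost without vehicle replicate 1 or hemin replicate 2 (edgeR adjusted p = 0.0759 and 0.0851). The neuron list itself did not pass among genes with a mean FPKM of at least 5 (camera adjusted p = 0.0673).

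Astrocyte, fibroblast and blood vessel markers completed the fixed lists. Of 15 tested astrocyte markers, 2 rose and 6 fell, 2 and 7 adjusted over the list alone, with a median log2 fold change of -0.25 (camera adjusted p = 0.0737). The list passed without hemin replicate 3 (camera adjusted p = 0.0369) and with quantile normalization (0.0374). Gja1, a gap junction protein, rose 2.47-fold and Clu, a secreted chaperone, 1.66-fold, while the glutamate transporter Slc1a2 fell 2.47-fold, the bicarbonate transporter Slc4a4 1.72-fold and the transcription factor Sox9 1.53-fold. The Clu call was lost with totals alone (edgeR adjusted p = 0.0694), with limma at a pseudocount of 0.1 (0.0591), and without vehicle replicate 1 or 2 (0.117 and 0.128) or hemin replicate 2 or 3 (0.0544 and 0.0808). Of 7 tested fibroblast and mural cell markers, 0 passed in edgeR, limma or DESeq2 without a block, and 0 had an unadjusted edgeR p under 0.05, which was also the outcome adjusted over the list alone (median 0.58, camera adjusted p = 0.298). With the replicate number as a block the list passed (camera adjusted p = 0.0472), and the collagen genes Col1a1 and Col3a1 were called higher (log2 fold change 1.24 and 1.06, edgeR adjusted p = 0.0257 and 0.0447). Both were below 3 FPKM on average in both groups, and Rgs5, a pericyte regulator of G proteins, stood at 3.21 ± 1.17 and 3.01 ± 1.24 FPKM. Of 5 tested endothelial markers, 3 rose, 5 adjusted over the list alone, with a median of 2.27 (camera adjusted p = 0.00107, and an adjusted p of 0.112 with an estimated correlation). Only 1 of the 5 averaged at least 1 FPKM with vehicle. Markers that low could enter the test through their hemin counts, while those that stayed low could not. The filter thus favours a rise, and the median and camera p of this list carry that bias. Pecam1, an adhesion molecule, rose from 0.153 ± 0.0153 to 2.34 ± 0.668 FPKM, and the receptors Tek and Kdr stayed below 1 FPKM on average, although they rose 12.6-fold and 4.82-fold. The endothelial transcripts Cldn5, Cdh5, Egfl7 and Emcn, too low to be tested singly, had 46 counts in all with vehicle and 56 with hemin, a ratio of 1.27 (95% counting interval 0.845 to 1.92). None of the 10 erythroid markers listed had enough counts to be tested.

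The files also hold unannotated features that the authors list apart from annotated genes. Of 678 such features in any library, 405 could be tested, and 153 passed, 121 higher and 32 lower with hemin, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these features alone. They took 19.0% to 22.6% of all counts per library. The 5 most abundant features, 4656 to 16212 bases long, held 84.6% to 90.5% of those counts and had log2 fold changes between -0.27 and 0.04. No position or sequence of these features was used here, so what they are is left open. The count of calls was 92 without vehicle replicate 1, 99 without vehicle replicate 2 and 96 without hemin replicate 2.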

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

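Of the alternatives reported here, library totals without TMM, leaving out genes at 0 in single libraries or in a whole group but well counted in others, and limma for the unannotated features were chosen only after the results were seen. Between 2974 and 4297 genes passed under the other filters, scalings, models and transcript choices, against 4077, and no called gene was called in the opposite direction in any of them or with a library left out. At an adjusted p below 0.01 the count was 1979 and at a change of at least 2-fold 1697, as stricter thresholds must give. With 1 library left out it ran from 2551 (without vehicle replicate 2) to 4530 (without hemin replicate 1). With an estimated correlation between genes 1 list passed (immediate early genes), against 19 with the preset value, 21 with fry, 16 among genes with a mean FPKM of at least 5 and 20 after quantile normalization, and 18 to 20 with 1 library left out. Why fewer lists pass with an estimated correlation was tested no further. The estimates rest on 6 libraries. Of the 18 lists that lost their call, 14 had an estimate above the preset 0.01 and 4 below it. In those 4 a higher correlation of their own genes cannot be the reason. The adjusted p with an estimated correlation therefore does not measure correlation alone. For unannotated features the count ran from 92 (without vehicle replicate 1) to 171 (without hemin replicate 1), with 143 and 146 for limma at pseudocounts of 0.1 and 1 and 169 without a filter.

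Among named genes, 4 that did not pass changed sign. Tfrc ranged from -0.048 (without hemin replicate 3) to 0.30 (without hemin replicate 1) on the log2 scale, with -0.02 without vehicle replicate 2 and -0.0017 without hemin replicate 2. Psmc2 ranged from -1.43 (without hemin replicate 3) to 0.26 (without vehicle replicate 2), Pcdh15 from -0.23 (without hemin replicate 2) to 1.22 (without hemin replicate 1), and Rgs5 from -0.30 (without vehicle replicate 2) to 0.25 (without hemin replicate 2). Rgs5 was also at 0.0041 after quantile normalization. The cause was not tested. Over all named genes and their alternatives, 1369 values kept direction and call, 105 lost the call, 11 gained it and 11 changed sign.

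The labels number the replicates alike in both groups but do not say that a number marks a shared culture. Same-numbered libraries correlated at 0.0631, 0.1 and 0.157 in their deviations from the group means. Of 6 libraries, 6 correlated best with their own number, a hint from the data and not from the design. The deviations cancel out within each group, so the 6 matches are not independent, and no chance level was computed. With the replicate number as a block, 3728 genes passed, 3500 of them among the 4077, together with 20 lists and 140 unannotated features. Totals of 6339966 to 6523639 annotated counts per library leave wide intervals for genes of few counts, such as Myod1 (ratio 520, 92.8 to 20566).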

Other observations

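The gene groups and single genes described in the next 2 paragraphs and in the last, the tests of microglial and endothelial markers, and the tests at like gene length were chosen only after the results were seen. Genes of Notch signalling and ligands of the EGF receptor family changed in both directions. Of 16 tested Notch genes, 7 fell and 1 rose (median log2 fold change -0.30, camera adjusted p = 0.0447 over the 6 groups tried, and an adjusted p of 0.247 with an estimated correlation). The median was -0.18 without hemin replicate 1 and -0.49 without hemin replicate 3, and the call was lost without hemin replicate 1 or vehicle replicate 3 (camera adjusted p = 0.0771 and 0.0531). The ligand Dll3 fell by 2.65 on the log2 scale, the targets Hes5 and Nrarp fell by 2.94 and 2.51 and Lfng, which modifies Notch receptors, fell by 1.64, while the ligand Jag1 rose by 1.30 ± 0.14 (SE, n = 3 per group). Of 10 ligands of the EGF receptor family, 5 rose and 2 fell (median 1.30, camera adjusted p = 0.00928, and an adjusted p of 0.345 with an estimated correlation). Hbegf rose by 1.83 from 15.3 ± 4.81 to 52.6 ± 6.51 FPKM, and Ereg and Epgn rose by 3.85 and 3.21 while staying below 2 FPKM on average. Areg had 3 counts with vehicle and 160 with hemin (ratio 55.7, 95% counting interval 18.7 to 273), and Tgfa fell by 1.17. Of 18 feedback regulators of MAP kinases, 7 rose and 2 fell (median 0.57, camera adjusted p = 0.0447, and an adjusted p of 0.39 with an estimated correlation), or 6 and 4 with totals alone. That call was lost without hemin replicate 1 or vehicle replicate 2 or 3 (camera adjusted p = 0.13, 0.0649 and 0.0697).

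Most cytosolic ribosomal protein genes rose, and clustered protocadherins, adhesion proteins of neural cells, fell. Of 81 ribosomal protein genes, 55 rose, 45 with totals alone, and 26 did not pass, with a median log2 fold change of 0.44 (camera adjusted p = 4.72e-12, and an adjusted p of 0.329 with an estimated correlation). Many of them have processed copies, so their counts are uncertain. Of 48 clustered protocadherins, 26 fell, 32 with totals alone, with a median of -0.74 (camera adjusted p = 1.48e-10, and an adjusted p of 0.0278 with an estimated correlation), although isoforms of a cluster share exons and reads could be split between them. Of 15 genes of the Id and BMP pathway, 4 rose and 4 fell (median -0.48, camera adjusted p = 0.333).

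The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large as the real one cannot fall below 0.1. The real split gave 4077 genes in edgeR, and the highest of the others 0. At an unadjusted edgeR p under 0.05 the others gave 55 to 391 genes, against 5570, and limma called 0 genes in each of them. For unannotated features the real split gave 153 and the highest other 1, and for lists 19 and 16. In each case 1 of 10 splits, the real one, was as large. With the preset correlation, lists thus pass in splits that hold no called gene. Every split but the real one puts both treatments on each side. Part of any hemin effect then stays between the sides and also widens the spread within them. Those splits are not free of an effect, and their counts give no rate of false calls.

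More annotated genes were listed in the hemin libraries (16719 to 16897) than in the vehicle libraries (15388 to 15500). Thinning every library to the same total left a gap of 1182 genes between the lowest hemin and the highest vehicle library, which argues against depth. Genomic DNA would add reads wherever a gene lies. Olfactory receptor genes with a count numbered 15, 18 and 22 in the vehicle and 46, 70 and 66 in the hemin libraries, which goes with such reads. Among genes at 0 in a pair of vehicle libraries the gain in the percent listed was 2.28 times (1.99 to 2.60, 95% bootstrap interval) as large within 20 kb of an expressed gene (mean FPKM of at least 5) as elsewhere, but these genes also had a longer median span (12881 against 5074 bases). Weighted to the same spans the ratio was 1.69 (1.46 to 1.93), and weighted to the same exonic lengths 2.21 (1.92 to 2.51), or 1.501 (1.31 to 1.73) without olfactory, vomeronasal, trace amine and taste receptor genes. The bound of 1.5 set beforehand for excluding DNA was thus not met once genes of like span were compared, and a contribution of DNA stays open. Where the expressed neighbour on the same strand lay upstream, the gain was 39.5 percentage points, against 16.1 where it lay downstream, a difference of 23.4 (13.9 to 32.9), or 22.1 (12.4 to 31.9) at like span. Reads spread evenly from DNA would not give such a difference by side. Transcription that runs past the ends of genes may therefore account for part of the added genes, while DNA as the source of others and induction of low genes by hemin remain open, the latter untested.

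Microglial markers rose in cultures that had been selected with beads for CD140a, which microglia lack. Csf1r, Cx3cr1, C1qa, C1qb and C1qc did not pass singly (edgeR adjusted p from 0.0985 to 0.209). Summed, they stood at 22.8 ± 8.06 CPM with vehicle and 38.3 ± 3.34 with hemin, a ratio of 1.68 (1.49 to 1.89, counting error only), with the lowest hemin library at 35.8 and the highest vehicle library at 28.8. Of the 15 tested markers, 0 stand on another fixed list, and 12 averaged at least 1 FPKM with vehicle. Absence of overlap by name does not separate them by function, since Cd68 is a lysosomal glycoprotein and the autophagy and lysosome list rose too. A loss of progenitor RNA alone would raise markers of all other cells alike. The median of microglial markers exceeded that of astrocyte markers by 1.07 (0.912 to 1.62) on the log2 scale. That interval resamples genes, which are not independent. Fibroblast and mural markers had a median of 0.58 and neuron markers one of -0.50. Whether the progenitors themselves transcribe astrocyte markers was not checked, so the difference cannot decide whether such a loss took place. A larger share of microglial RNA is a candidate explanation, and whether it reflects more microglia or more of these transcripts per cell is open.

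Endothelial markers had a high median that rests on few genes. Of the 5 tested markers, 0 stand on another fixed list, and 1 averaged at least 1 FPKM with vehicle. Markers that low could enter the test through their hemin counts, so the filter favours a high median. Cldn5, Cdh5, Egfl7 and Emcn summed to 46 counts with vehicle and 56 with hemin, a ratio of 1.27 (0.845 to 1.92), against 44 and 389 for Pecam1, Tek and Kdr, the 3 called members, a ratio of 9.23 (6.74 to 12.9). The first set was too low to be tested singly and the second was picked for its rise, so the contrast excludes nothing. Endothelial cells that stayed in the cultures despite the selection for CD140a and induction of single genes in the cultured cells are both possible explanations. Both stay open, the latter untested.

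In 193 genes a library had 0 counts where another of its group had at least 50, or a whole group had 0 where the other averaged at least 20, and 11 of the 166 tested were called. Kcna2, a potassium channel, had 895 counts with vehicle and 0 with hemin, at least 286-fold lower against a floor of 3 counts over the group. Zfp160 had 198, 121 and 179 counts with vehicle and 0 in each hemin library. Baz2b and Rbm15 had 0 in each vehicle library and 167, 200 and 206, and 65, 81 and 106, counts with hemin. An exact 0 can be a failed estimate, so these values are given without an interpretation.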
